A study of Arabidopsis thaliana with 12 samples.

How the data were processed

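RNA sequencing measured transcript levels in leaves of Arabidopsis thaliana Col-0 in 12 libraries, 4 each from plants mock-treated with 0.12% DMSO, plants infected with Alternaria brassicicola spores, and plants given spores with 10 µM DHEA. All 12 libraries are listed with 0.12% DMSO. Groups and replicate numbers came from the sample titles. One protocol gives a plant age of 10 days and another 7 days, followed by 2 days of adaptation. Harvest times, 1 h for mock treatment and 24 h for infection, come from the treatment protocol. The labels do not state that replicates are separate plants, so p-values measure the spread between these samples. RNA was extracted with TRIzol and libraries were made with an NEBNext Ultra II RNA kit, per the labels' protocols.

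The authors deposited a table of raw counts per gene, with a column per library. Reads were handled with bcl2fastq 2.20, FastQC 0.11.9, fastp 0.23.2, HISAT2 2.2.1, SAMtools 1.11 and featureCounts 2.0.1 on the genome build TAIR10, per the submitters' processing notes. The annotation, the strand setting and the treatment of reads that fit several places are not given in the sources used here. The deposited counts show part of it. There were 24 pairs of genes on opposite strands that share at least 95% of their exon bases and have enough counts, and all 24 had summed counts within 5% of each other, as counting without strand and to every overlapping gene gives. Overlapping and antisense genes therefore cannot be told apart, and near-identical copies such as the PDF1.2 defensins and tandem glutathione transferases are uncertain.

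Of 38618 genes in the table, 38074 matched a locus tag of the RefSeq annotation of TAIR10.1, which supplied symbols, products and coordinates. The 544 without a match held at most 0.057% of a library and kept their identifiers. Library totals were 45892092 to 62518823 counts. For genes with few counts, 95% intervals of count ratios are given, which cover counting error only. The smallest chi-square per degree of freedom between libraries of one group was 20.9, so replicates differed by more than counting noise and none were merged.

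Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). A quasi-likelihood model with a mean per group was fitted to all 12 libraries after TMM scaling and filterByExpr, which left 23355 genes, and the 3 comparisons are contrasts of it. Calls are at a Benjamini-Hochberg adjusted p under 0.05. Given levels are CPM over TMM-scaled library sizes. Principal components and library correlations used log2 CPM with a prior count of 2. Genes were said not to overlap where all 4 libraries of a group exceeded all 4 of the other. Scores of lists were compared by exact two-sided permutation.

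Before the data were examined, the design, the alternatives, the naming rule and 25 gene lists with 328 members were fixed. The lists cover defence hormones, phytoalexins, glucosinolates, sterols and steroids, detoxification, photosynthesis, senescence, stress, nutrients, the clock, handling, and root and shoot meristem markers. Of the members, 317 carry the same symbol or a synonym in the reference, 7 another spelling and 4 no symbol. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists, and again with an estimated correlation and with fry. Members were also adjusted over the list alone.

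Named genes follow a rule. It takes the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups, or the smallest p-values in each direction where few genes are called. From each list it takes a few called members, or values where none is called, starting from the lists with the smallest p, up to a limit on the number of names that was set after the data had been received. It always takes PDF1.2A, ORA59, PAD3, CYP71A13, WRKY33, PR1, VSP2, LOX2, ICS1, VEP1, SMT2, DWF4 and CPD. The other 8 low-oxygen genes, and PR3 between the infected groups, were added after their values were seen.

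Alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios scaling, library totals only, no low-count filter, a strict filter (1 CPM in 4 libraries), fits of the compared groups only, a block for replicate number, a 2-fold minimum, and leaving out each replicate in turn. Chosen after seeing the data were nuclear genes without ribosomal RNA, voom with quality weights, chloroplast share as a covariate and a test of gene families by product name. Correlations between comparisons that share DMSO libraries were set against 50 simulations without effects and DMSO libraries split 2 and 2. For genes called in both, 20 simulations of counts and the same splits were added after seeing the data.

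The tests were tried on counts simulated from the real means, library sizes and dispersions of 23355 genes, with 200 genes changed by known folds. For infected against DMSO, edgeR recovered 19.4% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 90.9% of those changed 4-fold, with 5 false calls. The real comparison called 8947 genes, far more than 200, which makes the adjusted threshold less strict. These shares therefore do not measure its power. For infected with DHEA against infected, edgeR made 4 false calls and DESeq2 33. Figures were drawn with matplotlib 3.10.9.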

Results

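RNA sequencing measured transcript levels in leaves of Arabidopsis thaliana, accession Col-0, in 3 groups of 4 libraries. The first group received a mock treatment with 0.12% DMSO, the solvent. The second was infected with spores of Alternaria brassicicola, a fungus that kills leaf tissue of the cabbage family and feeds on it. The third received spores together with 10 µM dehydroepiandrosterone (DHEA), a steroid known as a hormone precursor in mammals. All 3 groups are listed with 0.12% DMSO. Leaves of both infected groups were taken after 24 h, whereas the treatment protocol gives 1 h for the DMSO mock treatment, so infection and harvest time change together in every comparison with DMSO. Total counts ranged from 45892092 to 62518823 per library, and 23355 genes were tested.

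Infected and DMSO libraries lay further apart than libraries of one group did. Pearson's r of log2 CPM across genes was 0.979 to 0.986 among DMSO libraries, 0.962 to 0.977 among infected ones and 0.966 to 0.987 among infected ones with DHEA. It was 0.890 to 0.941 between DMSO and infected libraries, and 0.959 to 0.981 between infected libraries without and with DHEA. Chloroplast genes took 8.66% of the counts in replicate 4 of infected plants with DHEA, against 1.76% to 1.90% in the other 3, and ribosomal RNA genes 8.40% against 0.566% to 0.942%.

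**Figure D1:**
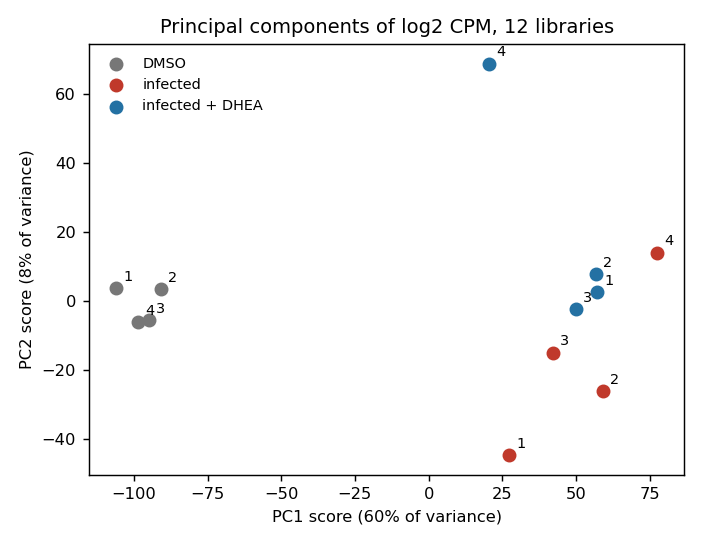
Scores of the 12 libraries on the first and second principal components of log2 CPM, with 1 point per library, coloured by group and numbered by replicate. The 4 DMSO libraries have PC1 scores of -106.09 to -90.72 and the 8 infected ones 20.46 to 77.55 (59.7% of variance), while PC2 (8%) sets apart infected with DHEA replicate 4, at 68.67.

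The comparison of infected with DMSO plants asked how leaf transcripts differ after infection with the fungus. Antimicrobial defence genes of the jasmonate and ethylene branch rose. PDF1.2A, a plant defensin gene (AT5G44420, chromosome 5, 17906968 to 17907638), went from 1.32 ± 1.33 CPM in DMSO to 1179 ± 509.6 CPM in infected leaves (SD, n = 4 each), a log2 fold change of 9.81 ± 0.98 (SE), with 3.29 CPM in DMSO replicate 4 and 0.3345 to 0.9176 CPM in the other 3. ORA59, a transcription factor gene that joins jasmonate and ethylene signals (AT1G06160, chromosome 1, 1882907 to 1883992), rose from 5.97 ± 0.788 to 54.3 ± 23.2 CPM. All 12 genes of the jasmonate-ethylene defence list rose, over all genes and adjusted over the list alone, with a median log2 fold change of 4.46. In camera, which compares a list with all other genes, its adjusted p was 9.76e-22, and 0.00431 with an estimated correlation, the only list of this comparison to pass both. PR4 and PR3, genes for chitin-binding and chitinase proteins, rose by 4.51 ± 0.23 and 4.86 ± 0.24 log2 units. PDF1.2A and PDF1.2C are near-identical copies and 33.1% of the exon bases of PR3 overlap AT3G12502, so the levels of these genes are uncertain.

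Genes of camalexin synthesis, the main phytoalexin of this species, rose together. All 10 measured genes passed over all genes and adjusted over the list alone, with a median log2 fold change of 3.67 (camera adjusted p = 3.43e-11, and adjusted p = 0.132 with an estimated correlation). PAD3, the cytochrome P450 gene of the last step (AT3G26830, chromosome 3, 9887917 to 9889791), rose from 3.47 ± 1.92 to 308 ± 172 CPM, and CYP71A13 from 0.466 ± 0.262 to 162 ± 111 CPM (SD, n = 4), with 22.1% of its exon bases shared with AT2G30766. WRKY33, a transcription factor gene acting on camalexin genes, rose by 2.82 ± 0.41 log2 units and GSTU4 by 4.71 ± 0.39. Indolic glucosinolates, defence compounds from the same precursor, had 9 genes higher and 1 lower of 12, or 11 and 1 adjusted over the list alone (camera adjusted p = 5.24e-06, and adjusted p = 0.253 with an estimated correlation). Aliphatic glucosinolates had 1 gene higher of 12 by both adjustments (camera adjusted p = 0.711).

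Most jasmonate and salicylic acid genes rose as well. The jasmonate response list had 12 of 14 genes higher, or 13 adjusted over the list alone (camera adjusted p = 9.34e-07, and adjusted p = 0.142 with an estimated correlation). Among them the repressor genes JAZ9 and JAZ8 rose by 2.14 ± 0.20 and 5.19 ± 0.56 log2 units, and the regulator MYC2, whose exon bases overlap AT1G32630 over 98.5%, by 1.299 ± 0.15. Jasmonate synthesis had 9 of 12 genes higher by both adjustments (camera adjusted p = 8.44e-05, and adjusted p = 0.201 with an estimated correlation), with the lipoxygenase gene LOX2 rising from 17.6 ± 5.53 to 165 ± 31.3 CPM. VSP2, a storage protein gene of the MYC2 branch, rose by 2.16 ± 0.54 log2 units, or 1.357 without infected replicate 3 (edgeR adjusted p = 0.0219). In the salicylic acid list 12 genes of 17 rose and 1 fell, or 13 and 1 adjusted over the list alone (camera adjusted p = 1.85e-05, and adjusted p = 0.132 with an estimated correlation). ICS1, which makes the salicylic acid precursor, rose from 5.69 ± 0.495 to 14.0 ± 2.23 CPM. PR1, a salicylic acid marker gene, stood at 0.226 ± 0.389 and 0.949 ± 0.606 CPM with a log2 difference of 2.08 ± 0.90 and an edgeR adjusted p of 0.086. It passed without DMSO replicate 4 (log2 difference 4.728, edgeR adjusted p = 0.000614) and by DESeq2 (0.0467) and limma-voom (0.0113).

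Most detoxification and senescence genes were higher in infected leaves. Of 27 xenobiotic detoxification genes 25 rose and 1 fell by both adjustments, with a median log2 fold change of 2.42 (camera adjusted p = 3.61e-18, and adjusted p = 0.106 with an estimated correlation). The glutathione transferase genes GSTU1, GSTU8 and GSTU2 rose by 4.21 ± 0.30, 2.64 ± 0.23 and 6.69 ± 0.51 log2 units, while GSTU5 fell from 148 ± 3.29 to 84.0 ± 9.60 CPM. These belong to a tandem family whose reads could be shared, and GSTU2 also shares 70.3% of its exon bases with AT2G29485. Senescence had 9 of 11 genes higher by both adjustments (camera adjusted p = 1.91e-07, and adjusted p = 0.106 with an estimated correlation). SAG13 rose from 1.07 ± 0.450 to 126 ± 28.0 CPM, the senescence regulator NAC092 by 2.66 ± 0.25 log2 units, and the chlorophyll b reductase gene NYC1 by 1.64 ± 0.19.

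The brassinosteroid list passed camera as lower. It had 0 genes higher and 6 lower of 12, or 1 and 7 adjusted over the list alone, with a median log2 fold change of -0.44 (camera adjusted p = 0.00189, and adjusted p = 0.132 with an estimated correlation). DWF4, a hydroxylase gene of brassinosteroid synthesis (AT3G50660, chromosome 3, 18813949 to 18817405), fell from 16.0 ± 3.20 to 4.93 ± 0.960 CPM, and CPD, of the same pathway, from 248 ± 23.7 to 120.3 ± 22.3 CPM. Sterol synthesis had 2 genes higher and 8 lower of 22 by both adjustments (camera adjusted p = 0.0953, 0.0314 without DMSO replicate 2 and 0.0403 without infected replicate 1), and its member SMT2 went from 110 ± 15.8 to 76.0 ± 13.7 CPM (edgeR adjusted p = 0.00688). Steroid conversion had 6 higher and 2 lower of 12 by both adjustments (camera adjusted p = 0.00719, and adjusted p = 0.106 with an estimated correlation). VEP1, a steroid reductase gene, stood at 285 ± 47.4 and 282 ± 20.03 CPM (edgeR adjusted p = 0.935).

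The 6 largest rises by the naming rule were in LCR67, CYP82C2, GLIP1, PXMT1, PDF1.2C and AT1G26390. LCR67, a defensin-like gene, had 3 counts over the 4 DMSO libraries and 9834 over the infected ones, a ratio of 3747 after scaling (95% counting interval 1282 to 18170). The P450 gene CYP82C2 rose by 11.51 ± 1.22 log2 units, the lipase gene GLIP1 by 10.80 ± 0.84, the methyltransferase gene PXMT1 by 10.68 ± 0.58, PDF1.2C by 10.21 ± 1.06 and the berberine bridge enzyme-like gene AT1G26390 by 9.85 ± 0.71. Genes of protein folding were among the 6 largest falls. AT1G07400, of the HSP20-like chaperones (chromosome 1, 2274926 to 2275783), fell from 410.2 ± 143 to 4.52 ± 1.84 CPM, HSP23.6-MITO from 16.9 ± 10.6 to 0.191 ± 0.121 CPM and the isomerase gene AT5G48570 from 579 ± 161 to 6.67 ± 1.27 CPM. The other 3 were the bHLH gene AT3G21330 (28.6 ± 4.16 to 0.0503 ± 0.101 CPM), FLP1 (23.5 ± 6.35 to 0.0753 ± 0.114 CPM) and AT1G64380 (28.9 ± 5.50 to 0.273 ± 0.197 CPM).

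**Figure D2:**
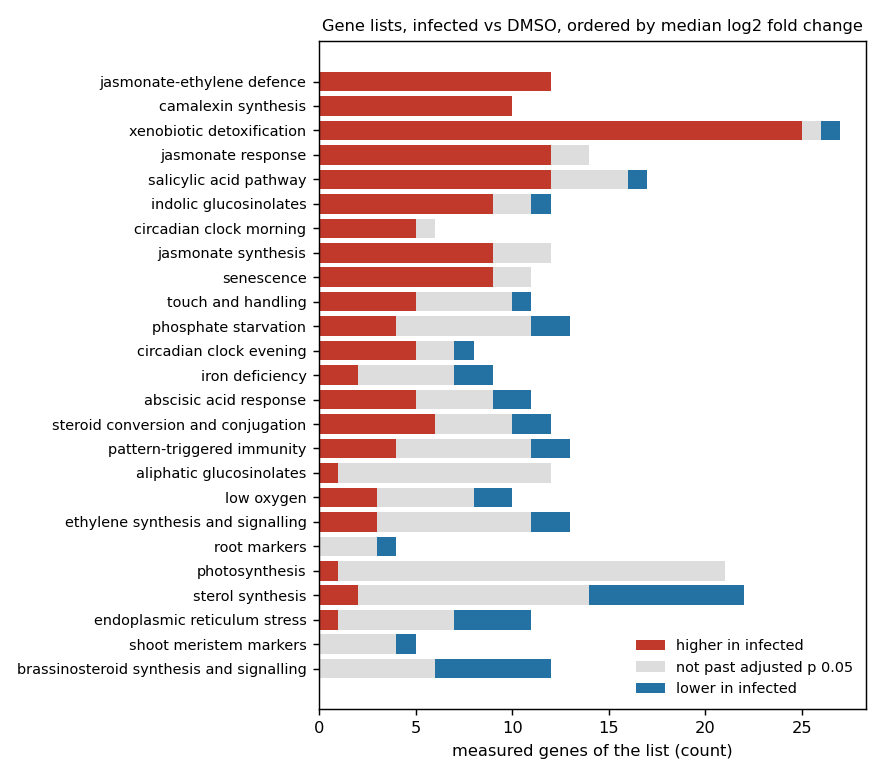
Numbers of measured genes per list (x axis) that were higher (red), lower (blue) or not past the threshold (grey) in infected against DMSO leaves by edgeR at an adjusted p of 0.05, with lists (y axis) ordered by their median log2 fold change. All 12 jasmonate-ethylene defence genes and all 10 camalexin genes were higher, and 6 of 12 brassinosteroid genes were lower.

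Lists that follow time of day and handling also differed between these groups. Morning clock genes were higher in 5 of 6 cases, or 6 adjusted over the list alone (camera adjusted p = 0.00226, and adjusted p = 0.267 with an estimated correlation). The evening clock had 5 higher and 1 lower of 8 (camera adjusted p = 0.0118, and adjusted p = 0.267 with an estimated correlation), and touch and handling 5 higher and 1 lower of 11 (camera adjusted p = 0.0125, and adjusted p = 0.267 with an estimated correlation), both by either adjustment. The remaining lists did not pass camera with all libraries. Their counts higher and lower were 1 and 4 of 11 for endoplasmic reticulum stress (adjusted p = 0.143, and 0.0218 without infected replicate 4), 4 and 2 of 13 for phosphate starvation (0.511), 4 and 2 of 13 for pattern-triggered immunity (0.53), 3 and 2 of 13 for ethylene (0.64), 3 and 2 of 10 for low oxygen (0.645) and 2 and 2 of 9 for iron deficiency (0.793), by either adjustment. Photosynthesis had 1 and 0 of 21, or 0 and 0 adjusted over the list alone (0.511), and abscisic acid response 5 and 2 of 11, or 5 and 3 adjusted over the list alone (0.907). Markers of other tissues gave 0 and 1 of 4 for root (0.64) and 0 and 1 of 5 for shoot meristem (0.32). Median and mean log2 fold changes differ in sign for ethylene (-0.081 and 0.22) and abscisic acid response (0.24 and -0.004).

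Over all genes, edgeR's quasi-likelihood test called 4718 genes higher and 4229 lower in infected leaves at a Benjamini-Hochberg adjusted p under 0.05, of which 2233 and 1221 changed at least 2-fold. The groups did not overlap for 36.66% of genes, where chance gives 2.86%. With library totals as the only scaling, the median log2 fold change of all genes was -0.13 and the share of higher genes among those called 38.0% in place of 52.7%. These differences belong to infection and harvest time together.

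**Figure D3:**
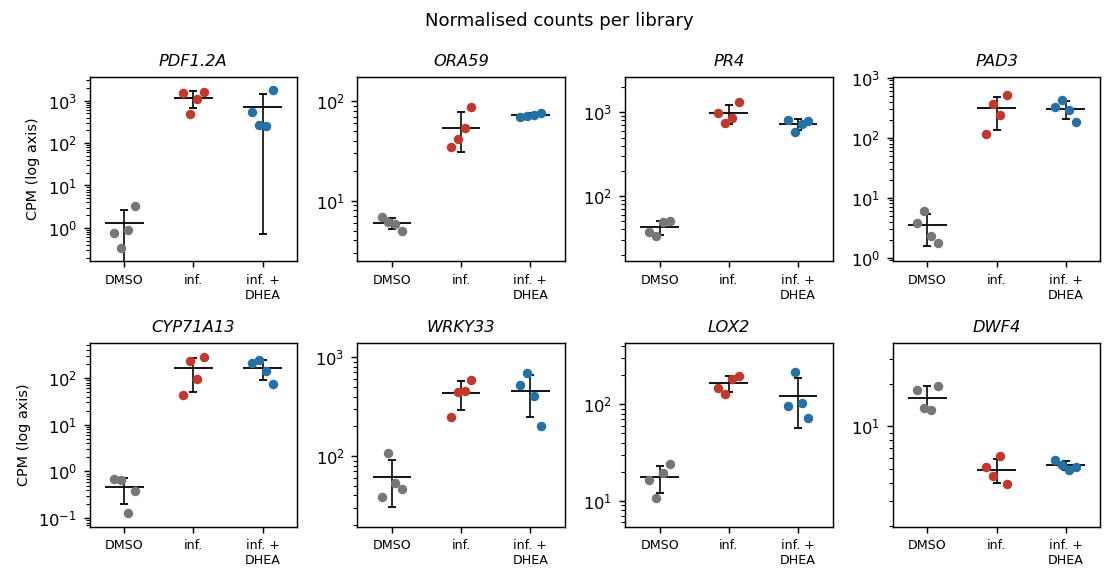
Normalised counts (CPM, log axis) of 8 genes in each library, with points for the 4 replicates per group, a line for the mean and a bar for the SD, shortened where it would pass 0. PDF1.2A, ORA59, PR4, PAD3, CYP71A13, WRKY33 and LOX2 lie higher in both infected groups than in DMSO and DWF4 lower, and the libraries without and with DHEA overlap for all 8 genes.

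The comparison of infected plants with and without DHEA asked what DHEA adds during infection. Genes of the response to low oxygen stood at higher levels with DHEA. HRA1, a transcription factor gene of that response (AT3G10040, chromosome 3, 3096345 to 3098417), was at 10.4 ± 7.57 CPM in infected leaves and 52.3 ± 20.2 CPM with DHEA (SD, n = 4), and LBD41 (AT3G02550, chromosome 3, 536500 to 538126) at 63.6 ± 44.9 and 183 ± 38.3 CPM. The oxygen-sensing cysteine oxidase gene PCO1 (AT5G15120, chromosome 5, 4898641 to 4900734) was at 2.52 ± 1.40 and 11.5 ± 3.61 CPM, and PCO2 (AT5G39890, chromosome 5, 15974270 to 15976270) at 1.21 ± 0.558 and 6.41 ± 2.71 CPM. The fermentation genes ADH1 and PDC1 were at 5.78 ± 0.632 and 0.679 ± 0.302 CPM without and 14.6 ± 6.17 and 1.90 ± 0.263 CPM with DHEA, and the haemoglobin gene HB1 at 9.39 ± 4.90 and 25.3 ± 3.44 CPM. For these 7 genes every library with DHEA lay above every infected library without it. PCO1 and PCO2 were highest in infected with DHEA replicate 4, at 16.85 and 10.45 CPM. The other libraries with DHEA had 9.186 to 10.39 and 4.63 to 5.335 CPM.

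Of the 10 measured low-oxygen genes, 0 passed over all genes and 7 were higher adjusted over the list alone. The list's median log2 difference was 1.46, with a camera adjusted p of 7.56e-17, and the call held with an estimated correlation (adjusted p = 0.0287) and in fry, which tests the list by itself (adjusted p = 0.0174). Mean log2 CPM of the list differed by 1.47 between the groups, with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 libraries allow (0.358 after Benjamini-Hochberg adjustment over 25 lists, of which too few reached that p for any to pass). HRE2 had a log2 difference of 1.00 ± 0.80, HRE1 of 0.17 ± 0.17 and SUS1 of 0.17 ± 0.25, and their libraries overlapped. PCO1 and PCO2 followed from the naming rule, whereas the other 8 low-oxygen genes were named after their values were seen. Over all genes PCO1, PCO2, HRA1 and LBD41 passed in edgeR without infected replicate 4 (adjusted p = 0.0131, 0.0237, 0.032 and 0.0331). With chloroplast share, highest in infected with DHEA replicate 4, as a covariate, the list's median was 1.33.

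**Figure D4:**
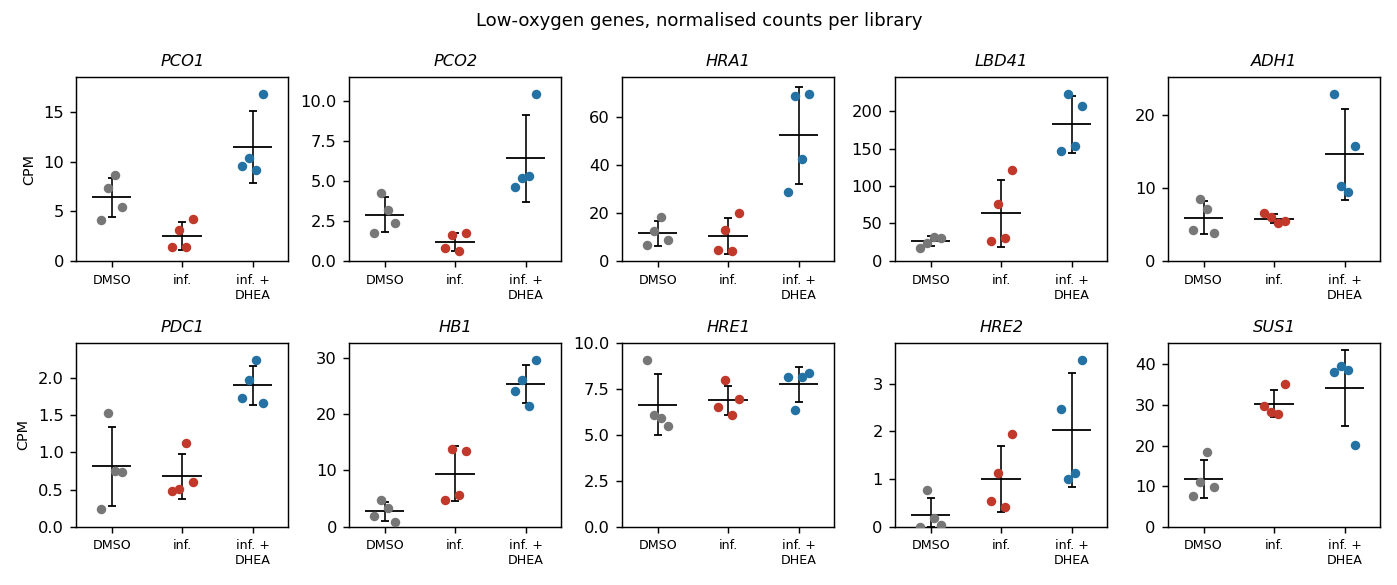
Normalised counts (CPM, linear axes from 0) of the 10 measured low-oxygen genes in each library, with points for the 4 replicates per group, a line for the mean and a bar for the SD. For PCO1, PCO2, HRA1, LBD41, ADH1, PDC1 and HB1 the 4 libraries with DHEA lie above the 4 infected libraries without it, while those of HRE1, HRE2 and SUS1 overlap.

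The lists of jasmonate-ethylene defence and camalexin genes did not pass camera between infected leaves without and with DHEA with all libraries, while with a block for replicate number the jasmonate-ethylene list passed as lower (median -0.17, camera adjusted p = 0.0187). The 12 jasmonate-ethylene defence genes had a median log2 difference of -0.16 (camera adjusted p = 0.432), with 0 past the threshold over all genes and 1 lower adjusted over the list alone, and the 10 camalexin genes one of -0.037 (0.952). PDF1.2A was at 1179 ± 509.6 CPM without and 717 ± 727 CPM with DHEA, where replicate 4 had 1788 CPM and the other 3 254.3 to 552.7 CPM. Its log2 difference was -0.72 ± 0.67 with that library and -1.719 without it (edgeR adjusted p = 0.777 and 0.538). PR3, named after its values were seen, was at 59.4 ± 13.2 CPM without and 33.7 ± 9.04 CPM with DHEA, with all 4 DHEA libraries below all 4 others. It passed adjusted over the list alone (adjusted p = 0.0144) and over all genes in DESeq2 (0.0284) but not in edgeR (0.276), with 0.0284 to 0.528 over all alternatives. ORA59 was at 54.3 ± 23.2 and 72.7 ± 3.34 CPM, PAD3 at 308 ± 172 and 306 ± 98.5 CPM and CYP71A13 at 162 ± 111 and 166 ± 75.5 CPM. WRKY33 differed by 0.08 ± 0.38, PR1 by -0.64 ± 0.84, VSP2 by -0.29 ± 0.51, LOX2 by -0.44 ± 0.31 and ICS1 by -0.13 ± 0.12 log2 units. The steroid genes VEP1, SMT2, DWF4 and CPD differed by -0.018 ± 0.13, 0.36 ± 0.13, 0.11 ± 0.17 and 0.14 ± 0.14. The lowest edgeR adjusted p of the 13 genes always named was 0.427, and ORA59 passed when infected replicate 4 was left out (edgeR adjusted p = 0.0436).

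Another 5 lists passed camera with lower levels under DHEA, none of them with an estimated correlation. Exact two-sided permutation of list scores gave p = 0.4 for xenobiotic detoxification and 0.0571 for the morning clock. It gave 0.114 for iron deficiency and 0.286 for abscisic acid response. After Benjamini-Hochberg adjustment these were 0.918, 0.476, 0.712 and 0.918. Xenobiotic detoxification had a median log2 difference of -0.32 (camera adjusted p = 5.2e-06, and adjusted p = 0.556 with an estimated correlation), with 3 of 27 genes lower adjusted over the list alone. The list's median was -0.151 without infected with DHEA replicate 4 (camera adjusted p = 0.0376) and -0.182 without infected replicate 4 (0.026). Its glucosyltransferase genes UGT73B3 and UGT75D1, with 15% and 12.1% of exon bases in other genes, were at 34.5 ± 2.96 and 161 ± 28.6 CPM without and 22.8 ± 4.52 and 117 ± 6.52 CPM with DHEA. The morning clock had a median of -0.61 (camera adjusted p = 5.2e-06, and adjusted p = 0.35 with an estimated correlation) and 2 of 6 genes lower adjusted over the list alone, with PRR9 at 7.18 ± 2.53 and 2.00 ± 1.06 CPM and RVE1, which overlaps AT5G17305 over 11.2% of exon bases, at 9.12 ± 1.31 and 5.87 ± 1.2 CPM. Senescence had a median of -0.27 (camera adjusted p = 0.000671, and adjusted p = 0.35 with an estimated correlation) and 1 of 11 genes lower adjusted over the list alone, with SAG13 at 126 ± 28.0 and 64.9 ± 23.0 CPM and SGR1 at 26.7 ± 3.50 and 18.1 ± 5.08 CPM. Mean log2 CPM of the senescence list differed by -0.392. Its exact two-sided permutation p was 0.0286, the same as for low oxygen (0.358 after Benjamini-Hochberg adjustment). That list did not pass without infected with DHEA replicate 4 (median -0.142, camera adjusted p = 0.0654).

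Iron deficiency had a median log2 difference of -0.22 (camera adjusted p = 0.000982, and adjusted p = 0.35 with an estimated correlation), with FRO3 at 68.8 ± 4.86 and 59.0 ± 3.08 CPM and IMA1 at 0.562 ± 0.399 and 0.175 ± 0.131 CPM. The iron list's median was -0.728 without infected with DHEA replicate 4 (camera adjusted p = 0.00274) and -0.379 without infected replicate 2 (6.3e-07), and it did not pass with the strict filter (0.0862). Abscisic acid response had a median of -0.29 (camera adjusted p = 0.0237, and adjusted p = 0.35 with an estimated correlation), with HAB1 at 20.7 ± 2.88 and 16.1 ± 2.54 CPM and COR15A at 6.52 ± 9.64 and 1.29 ± 0.455 CPM, where infected replicate 3 had 20.95 CPM and the other 3 infected libraries 1.121 to 2.631 CPM. The abscisic acid list did not pass without infected replicate 3 (median -0.184, camera adjusted p = 0.364) or without infected with DHEA replicate 4 (0.0676), and none of its genes or of the iron genes passed over all genes or adjusted over the list alone.

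Other lists did not pass camera here with all libraries. The adjusted p was 0.128 for endoplasmic reticulum stress, where PDIL1-1 was at 176 ± 30.2 and 147 ± 11.6 CPM and CRT2 at 168 ± 35.9 and 141 ± 11.2 CPM. It was 0.312 for phosphate starvation, 0.463 for sterol synthesis, 0.463 for pattern-triggered immunity, 0.489 for ethylene, 0.731 for the evening clock, 0.865 for indolic and 0.981 for aliphatic glucosinolates, 0.831 for root and 0.779 for shoot meristem markers. Jasmonate synthesis, jasmonate response, salicylic acid, brassinosteroids, steroid conversion, photosynthesis and touch each had 0.432. Adjusted over the list alone, steroid conversion had 1 gene lower and the evening clock 1 higher and 2 lower, and the others of this paragraph 0. Some passed with a library left out. As lower, these were jasmonate synthesis without infected replicate 1 (camera adjusted p = 0.0368) or infected with DHEA replicate 2 (0.0488), photosynthesis without infected replicate 4 (0.00122), and endoplasmic reticulum stress without infected replicate 3 (0.000808) or infected with DHEA replicate 1 (0.0458) or 2 (0.0207). As higher, these were jasmonate response without infected replicate 3 (0.0236) or infected with DHEA replicate 4 (0.0301), and ethylene (0.0195) and touch (0.0162) without infected with DHEA replicate 4. The median, mean and test differ in sign for steroid conversion (-0.035, 0.016, lower), indolic glucosinolates (0.059, 0.003, lower) and aliphatic glucosinolates (0.026, 0.065, lower).

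By smallest p, the genes on the higher side were AT3G19680 (35.3 ± 9.69 CPM without and 83.1 ± 11.1 with DHEA), the transcription factor gene MYB70 (19.97 ± 3.37 and 35.1 ± 2.54), PCO2, KINESIN-12B (5.66 ± 0.475 and 10.7 ± 2.46) and AT5G51795 (2.65 ± 0.250 and 4.81 ± 0.578). On the lower side were AT2G29165 (11.9 ± 3.33 and 3.74 ± 1.22), AT4G38860 of the SAUR-like auxin-responsive family (12.2 ± 1.46 and 5.28 ± 1.69), NAC083 (105 ± 8.63 and 70.8 ± 3.74), MYB59 (22.8 ± 5.80 and 9.98 ± 2.40) and GLK2, a regulator of chloroplast development (60.8 ± 10.7 and 33.8 ± 4.79). Their edgeR adjusted p was 0.109 or 0.118, and DESeq2, voom with quality weights and edgeR without infected replicate 4 each called all 10.

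Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes, with a lowest adjusted p of 0.109, and limma-voom 0, while 2244 genes had an unadjusted p under 0.05 against 1168 from chance. DESeq2 called 75 higher and 75 lower, and voom with quality weights 36 and 15. In edgeR, 57 higher and 36 lower genes were called when infected replicate 4 was left out, against 0 and 1 when replicate 4 of infected with DHEA was. Chloroplast-encoded genes made up 24 of the 57 higher genes, 16 of the 36 from quality weights and 3 of the 75 from DESeq2. Chloroplast genes took 0.436%, 0.570%, 1.63% and 3.09% of the counts in infected replicates 1 to 4, and 1.76% to 8.66% with DHEA. Without infected replicate 4, every library with DHEA lay above every infected one in this share. The groups did not overlap for 4.66% of genes, where chance gives 2.86%. The values from chance, 1168 and 2.86%, are averages. Genes are not independent of each other, so a single grouping can lie far from them. Without infected replicate 2 or 4, 1666 and 3127 genes had an unadjusted p under 0.05. Neither excess therefore shows an effect of DHEA. In counts simulated for this comparison over 23355 genes, edgeR recovered 13.4% of genes changed 1.5-fold. It recovered 68.7% of those changed 2-fold and 93.9% of those changed 4-fold. The real comparison called 0 genes, fewer than in the simulated counts, which makes its adjusted threshold stricter. These shares therefore do not measure its power.

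The comparison of infected plants with DHEA and DMSO plants gave infection, DHEA and harvest time together. Defence genes rose here too. All 12 jasmonate-ethylene defence genes and all 10 camalexin genes were higher by both adjustments, with medians of 4.06 (camera adjusted p = 3.1e-23, and adjusted p = 0.00113 with an estimated correlation) and 3.68 (camera adjusted p = 2.07e-12, and adjusted p = 0.145 with an estimated correlation). PDF1.2A rose from 1.32 ± 1.33 CPM in DMSO to 717 ± 727 CPM, a log2 fold change of 9.09, or 8.1 without infected with DHEA replicate 4. ORA59 rose from 5.97 ± 0.788 to 72.7 ± 3.34, PAD3 from 3.47 ± 1.92 to 306 ± 98.5 and CYP71A13 from 0.466 ± 0.262 to 166 ± 75.5 (SD, n = 4). WRKY33 rose by 2.90 ± 0.41, PR4 by 4.09 ± 0.22, PR3 by 4.04 ± 0.23 and GSTU4 by 4.47 ± 0.38 log2 units. Low-oxygen genes rose in 8 of 10 cases, or 9 adjusted over the list alone, with a median of 1.43 (camera adjusted p = 0.000329, and adjusted p = 0.179 with an estimated correlation).

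Jasmonate response had 12 of 14 genes higher by both adjustments (camera adjusted p = 2.31e-08, and adjusted p = 0.145 with an estimated correlation), with JAZ9, JAZ8 and MYC2 rising by 2.41 ± 0.20, 5.52 ± 0.57 and 1.59 ± 0.15 log2 units. Jasmonate synthesis had 9 of 12 higher by both adjustments (camera adjusted p = 0.000224, and adjusted p = 0.207 with an estimated correlation), and LOX2 rose by 2.79 ± 0.33, VSP2 by 1.87 ± 0.54 and ICS1 by 1.17 ± 0.12. In the salicylic acid list 12 of 17 rose and 1 fell by both adjustments (camera adjusted p = 2.46e-05, and adjusted p = 0.145 with an estimated correlation). PR1 differed by 1.43 ± 0.91 (edgeR adjusted p = 0.244) and by 4.081 without DMSO replicate 4, where it passed (0.0018), as it did by limma-voom (0.0266). Indolic glucosinolates had 9 higher and 1 lower of 12 by both adjustments (camera adjusted p = 4.92e-06, and adjusted p = 0.212 with an estimated correlation), where the methyltransferase gene IGMT1 and the regulator MYB51 rose by 3.60 ± 0.33 and 3.54 ± 0.39 and the regulator MYB34 fell from 4.68 ± 1.204 to 0.968 ± 0.417 CPM.

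Xenobiotic detoxification had 24 genes higher and 1 lower of 27 by both adjustments (camera adjusted p = 4.03e-14, and adjusted p = 0.145 with an estimated correlation). GSTU1, GSTU2 and GSTU3 rose by 3.57 ± 0.29, 5.79 ± 0.51 and 7.78 ± 0.78 log2 units, and GSTU5 fell from 148 ± 3.29 to 74.6 ± 18.3 CPM. Senescence had 7 higher and 1 lower of 11 by both adjustments (camera adjusted p = 1.89e-05, and adjusted p = 0.145 with an estimated correlation). Brassinosteroid genes fell in 6 of 12 cases by both adjustments (camera adjusted p = 0.00385, and adjusted p = 0.145 with an estimated correlation), DWF4 from 16.0 ± 3.20 to 5.31 ± 0.387 CPM and CPD from 248 ± 23.7 to 132 ± 15.2 CPM. VEP1 and SMT2 differed by -0.034 ± 0.13 and -0.18 ± 0.13 log2 units, with edgeR adjusted p of 0.872 and 0.336. Steroid conversion had 5 higher, or 6 adjusted over the list alone, and 2 lower of 12 (camera adjusted p = 0.0104, and adjusted p = 0.145 with an estimated correlation).

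Endoplasmic reticulum stress genes were higher in 1 and lower in 6 of 11 cases, or 1 and 7 adjusted over the list alone (camera adjusted p = 0.0167, and adjusted p = 0.539 with an estimated correlation), and did not pass without infected with DHEA replicate 4 (0.0893). Touch and handling had 7 higher and 2 lower of 11 (camera adjusted p = 0.00288, and adjusted p = 0.207 with an estimated correlation) and the evening clock 4 higher of 8 (camera adjusted p = 0.0115, and adjusted p = 0.257 with an estimated correlation), by either adjustment. The other lists did not pass camera, and their counts were the same by either adjustment. They included the morning clock (2 of 6 higher, adjusted p = 0.153) and sterol synthesis (2 higher and 7 lower of 22, 0.153). Also among them were shoot meristem markers (1 of 5 lower, 0.196), photosynthesis (1 of 21 higher, 0.233) and abscisic acid response (2 and 3 of 11, 0.32). Likewise ethylene (3 and 1 of 13, 0.361), iron deficiency (1 and 2 of 9, 0.361), root markers (1 of 4 lower, 0.489), pattern-triggered immunity (4 and 2 of 13, 0.633), aliphatic glucosinolates (1 of 12 higher, 0.667) and phosphate starvation (3 and 1 of 13, 0.717) did not pass. Median and mean differ in sign for pattern-triggered immunity (-0.053 and 0.58), sterol synthesis (-0.19 and 0.024) and phosphate starvation (-0.014 and 0.35).

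The 6 largest rises over DMSO were in LCR67 (3 counts in DMSO and 8888 with DHEA, a ratio of 3258 with a 95% counting interval of 1115 to 15800), CYP82C2 (11.36 ± 1.22 log2 units), PXMT1 (10.48 ± 0.58), GLIP1 (10.37 ± 0.84), the indolic glucosinolate regulator MYB122 (9.85 ± 0.86) and the beta-glucosidase gene BGLU27 (9.78 ± 1.15). The 6 largest falls were in FLP1 (-9.35 ± 0.74), AT3G21330 (-8.04 ± 0.49), AT1G05767 (-7.53 ± 0.52), the small heat shock protein genes HSP17.6II (-6.66 ± 0.39) and HSP23.6-MITO (-6.58 ± 0.55), and AT1G07400 (-6.53 ± 0.42). All exon bases of AT1G05767 overlap AT1G22810, so its counts cannot be assigned to it alone. edgeR's quasi-likelihood test called 4258 genes higher and 3695 lower at a Benjamini-Hochberg adjusted p under 0.05, of which 2048 and 1179 changed at least 2-fold. The groups did not overlap for 34.0% of genes, where chance gives 2.86%. With library totals as the only scaling, the median of all genes was -0.15 and the share of higher genes among those called 33.9% in place of 53.5%.

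Genes changed in much the same directions in both infected groups relative to DMSO. Of the genes called, 3683 were higher in both comparisons, where independent lists of these lengths would share 860, and 2988 were lower in both (669), while 2 were called in opposite directions. Those independent values leave out the shared DMSO libraries. In 20 simulations without effects 0 genes were higher and 0 lower in both, since few are called without effects, so this does not show how much the shared libraries add. With different DMSO libraries for each comparison, over 6 ways of splitting them, 2271 to 2357 genes were higher in both (independent lists 410 to 495) and 1760 to 1875 lower (295 to 361). The log2 fold changes correlated across genes at r = 0.942. Both comparisons use the same DMSO libraries, and groups simulated without effects gave r = 0.500. With different DMSO libraries for each comparison, r was 0.868 on average and 0.851 to 0.885 over 6 ways of splitting them. The covariance of log2 CPM differences was 0.883, against 0.0439 in the simulation, a difference of 0.839. Genes are not independent replicates, so these correlations describe the genes measured here.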

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

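The tests in this part were chosen only after the result was seen, except leaving out a replicate and the count of splits for the morning clock list, which were planned. A value far from the other 3 of its group was found in 22 of 273 groups of libraries, where chance gives about 1 in 20. Of these, 9 were in infected with DHEA replicate 4. That library had 8.66% of its counts in chloroplast genes, 0.121% in mitochondrial genes, 8.40% in ribosomal RNA genes and 14.7% in its 10 most abundant genes. The other 3 had 1.76% to 1.90%, 0.0309% to 0.0403%, 0.566% to 0.942% and 6.18% to 6.89%. Its mean log2 CPM of senescence genes was 5.52, against 6.231 to 6.328. GSTU1 and SUS1 were lower in it, at 9.779 and 20.23 CPM against 15.34 to 15.91 and 38.11 to 39.67 CPM. PCO2 and PCO1 were higher, at 10.45 and 16.85 CPM against 4.63 to 5.335 and 9.186 to 10.39 CPM.

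Single libraries held such values for other genes. Outside infected with DHEA replicate 4 these were about as frequent as chance gives. The values of LCR67, PXMT1, AT3G21330 and FLP1 lay close to 0. In DMSO replicate 2 the xenobiotic detoxification genes had a mean log2 CPM of 2.501, PXMT1 was at 0.1115 CPM and GSTU4 at 10.81 CPM. LCR67 was at 0.05618 CPM in DMSO replicate 3 and 0 in the other DMSO libraries. PR1 was at 0.8087 CPM in DMSO replicate 4, against 0 to 0.05925 CPM, and MYC2 at 30.88 CPM, against 28.12 to 28.37 CPM. In infected replicate 1 jasmonate synthesis genes had a mean log2 CPM of 5.467 and JAZ9 131.5 CPM. AT3G21330 was at 0.201 CPM and COR15A at 20.95 CPM in infected replicate 3. With DHEA, FLP1 was at 0.1409 CPM in replicate 1, and RVE1 at 4.088 CPM and HRE1 at 6.342 CPM in replicate 2.

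The first pattern is the higher level of low-oxygen genes with DHEA. Without infected with DHEA replicate 4 the list's median log2 difference was 1.39, which argues against that library as the whole source. Only 1 of 35 splits of the 8 infected libraries, the real one, gave a median as far from 0 (1.46, highest other 1.16). Only that split gave any of the 25 lists a median as far from 0 (highest other 1.16). This argues against chance but does not exclude it, as 1 of 35 is the smallest share that these splits can give. A stronger or weaker infection cannot be told apart from an effect of DHEA: the jasmonate-ethylene defence genes had a median of -0.16, and that 7 of the 10 genes had all 4 DHEA libraries above all 8 others does not decide, as DMSO was taken at 1 h. That DHEA itself may raise these genes remains a hypothesis.

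A second pattern is the lower level of morning clock genes with DHEA. Without infected with DHEA replicate 4 the median was -0.46 (camera adjusted p = 0.000181), which argues against that library as the whole source. Chance is not excluded, since 3 of 35 splits, the real one included, gave a median as far from 0 (-0.61, highest other -0.80). A harvest at another time of day cannot be told apart from an effect of DHEA, because the labels give no time of day and the evening clock genes, with a median of -0.048, moved both ways.

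The last pattern is the lower level of HSP20-like chaperone genes in both infected groups than in DMSO, with 12 and 10 of 28 genes lower. In 10 of these genes all 4 DMSO libraries lay above all 8 others, which argues against a single DMSO library as the source. The 10 genes lower in both infected groups are what a harvest at 1 h in place of 24 h could give as well as infection, and these cannot be told apart because they change together.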

How the results depend on the processing

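Nuclear genes without ribosomal RNA, voom with quality weights and chloroplast share as a covariate were chosen after seeing the data. Across alternatives, 165 values that answer a comparison kept their size or call and 23 moved. For named genes and lists, 2519 values kept direction and side of the threshold, 51 passed newly, 42 no longer passed and 24 changed sign.

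A 2-fold minimum left 2233 higher and 1221 lower genes in infected against DMSO, and 2048 and 1179 in infected with DHEA against DMSO, since it asks for more. With an estimated correlation, 1 list passed in each comparison in place of 13, 6 and 14, and fry left 1 between the infected groups. Against DMSO, fry passed every list that camera had called, and some others. Those were sterol synthesis in infected leaves (fry adjusted p = 0.0144) and, with DHEA, sterol synthesis (0.0435), the morning clock (0.0374) and shoot meristem markers (0.0327). Unlike camera, fry does not compare a list with other genes. Library totals only gave 6059 lower genes in infected with DHEA against DMSO. Under that scaling the medians of pattern-triggered immunity, low oxygen and aliphatic glucosinolates in infected against DMSO, and of ethylene in infected with DHEA against DMSO, changed sign, and none of these lists was called.

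Between the infected groups DESeq2 called 75 higher and 75 lower genes and voom with quality weights 36 and 15, where edgeR called 0 (2244 at an unadjusted p under 0.05) and limma-voom 0. The cause was not tested. Leaving out a replicate gave 0 to 57 higher and 0 to 36 lower genes, the most without infected replicate 4. The correlation of log2 fold changes was 0.9597 with the strict filter, 0.8681 with DMSO libraries split and 0.9104 to 0.9425 with a replicate left out.

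Sign changes were all in differences that did not pass, and their cause was not tested. For PAD3 between the infected groups (-0.008) limma-voom gave 0.148, quality weights 0.388, the replicate block 0.014 and fits without a replicate -0.29 to 0.357. Fits without a replicate gave -0.291 to 0.442 for CYP71A13, -0.2 to 0.319 for WRKY33, -0.743 to 0.517 for VSP2 and -0.083 to 0.036 for VEP1, where quality weights gave 0.052. Against DMSO they gave VEP1 -0.131 to 0.075 for infected plants and -0.149 to 0.053 with DHEA.

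Among named results, iron deficiency between the infected groups did not pass with the strict filter (camera adjusted p = 0.0862), BGLU27 against DMSO with limma-voom (adjusted p = 0.0641) and VSP2 with DHEA against DMSO with quality weights (voom adjusted p = 0.0858).

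Replicate numbers did not pair the libraries. Same-numbered libraries had deviations correlated at -0.111 to 0.149, and 3 of 12 correlated best with their own number. The replicate block gave 4321 higher and 3785 lower genes in infected against DMSO and 0 in edgeR between the infected groups, where 2069 had an unadjusted p under 0.05.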

Other observations

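The counts of splits and the tests of families in this part were chosen only after the result was seen. Other splits of the 8 libraries of a comparison into 4 and 4 were tested in the same way, 35 each with the real one. For infected against DMSO, 1 split, the real one, called as many genes as 8947 (highest other 0). For infected with DHEA against DMSO 1 called as many as 7953 (highest other 24). Both argue against chance but do not exclude it, as 1 of 35 is the smallest share possible. The other splits mix the groups, which adds the real difference to their spread and lowers their calls. Between the infected groups edgeR called 0 genes (2244 at an unadjusted p under 0.05), so all 35 splits called as many (highest other 8). DESeq2 called 150 genes there, and 5 of 35 splits called as many, with a highest other of 580, so chance is not excluded and the split with 580 points to a structure of the samples other than treatment. All 4 other splits with as many parted infected replicate 4 from infected replicates 1 and 3. That library was exchanged with infected with DHEA replicate 4 (580 genes), 3 (564) or 1 (209), or together with infected replicate 2 for DHEA replicates 3 and 4 (439), while its exchange with DHEA replicate 2 gave 13.

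For numbers of lists called by camera with a preset correlation, chance is not excluded. As many lists were called in 6 splits for infected against DMSO (real 13, highest other 14), in 25 between the infected groups (real 6, highest other 18) and in 3 for infected with DHEA against DMSO (real 14, highest other 15). Against DMSO these counts say little about chance, because splits that exchange 1 library keep part of the real difference. They called 8 to 14 lists for infected and 6 to 15 for infected with DHEA, and the 18 splits that exchange 2 called 0 to 10 and 0 to 11.

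Families of genes with the same product name and at least 8 tested genes, 350 in all, were tested after the data had been examined, and none passed with an estimated correlation. In infected against DMSO leaves, 29 of 47 MATE efflux genes rose and none fell (2 did without infected replicate 3 and 1 without replicate 4), with a median log2 fold change of 0.85 (camera adjusted p = 1.63e-11, and adjusted p = 0.548 with an estimated correlation). Berberine bridge enzyme-like genes rose in 12 of 20 cases (camera adjusted p = 5.37e-05, and adjusted p = 0.758 with an estimated correlation). HSP20-like chaperone genes fell in 12 of 28 cases (camera adjusted p = 4.3e-07, and adjusted p = 0.726 with an estimated correlation). Among 3-ketoacyl-CoA synthases, enzymes of wax and long fatty acid synthesis, 1 rose and 10 fell of 19 (camera adjusted p = 0.000285, and adjusted p = 0.758 with an estimated correlation), and among SAUR-like auxin-responsive genes 4 rose and 29 fell of 64 (camera adjusted p = 0.00369, and adjusted p = 0.93 with an estimated correlation).

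Between the infected groups 13 families passed camera with a preset correlation, 8 higher and 5 lower with DHEA, and 0 with an estimated correlation. The largest median log2 difference was 0.76 for 16 NADH dehydrogenase subunits (camera adjusted p = 0.00361), of which 8 are chloroplast and 8 mitochondrial genes. It was 0.154 without infected with DHEA replicate 4 (adjusted p = 0.405), 1.235 without infected replicate 4 (2.18e-09) and 0.574 without infected replicate 1 (0.0615). For 29 histone genes the median was 0.235 (0.000944), and 0.073 without infected with DHEA replicate 4 (0.269). On the lower side, the 14 glutathione transferases with TAU in capitals in their product name had a median of -0.336 (0.00971). They did not pass without infected with DHEA replicate 4 (0.2) or infected replicate 4 (0.157). Another 11, with tau in lower case, formed a separate family, which was not among the 13 that passed. The lowest median, -0.4 for 8 RWP-RK genes (0.000944), passed without each of the 8 libraries, the least without infected with DHEA replicate 4 (0.0156).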
